A study of Saccharomyces cerevisiae with 22 samples.

How the data were processed

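The series profiles RNA of haploid MATa yeast strains with rDNA arrays of known length, in libraries of polyA-selected RNA (10 strains of normal and 2 of low polyA recovery, as the labels say) and in libraries of total RNA made without polyA selection (10 strains, the same as those of normal recovery). Per the labels' protocols, RNA was taken with acid phenol, cleaned on columns and made into strand-specific libraries. Per the submitters' processing notes, bcl2fastq, Salmon 0.8.1 and DESeq2 were used on the sacCer3 build; their settings are not given in the sources used here.

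The polyA files hold TPM as deposited, with 5919 entries that sum to 1000000 in each library, so they keep no depth. The 96 spike-in entries are listed at 0 throughout. The deposited total RNA files hold a normalised signal for 18222 features. Each library's values are whole multiples of its own smallest value: 100% came out within 0.001 of a whole number, and the steps are the reciprocals of the DESeq2 size factors of the recovered reads. The values are thus read counts divided by a size factor. Reads recovered in this way gave the depths and the rRNA shares. Copies with identical sequence hold equal values in both assays: 14 of the tested polyA genes and 36 of the tested total RNA features have the same values as another one. The deposited values do not tell whether a read was split between such copies or counted at each.

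The main tests, their alternatives, the gene lists and the rule for named genes were fixed before the data were examined. In polyA RNA a linear trend of log2(TPM + 1) on repeat number was fitted with limma 3.58.1 in R 4.3.3, with moderation that follows abundance and is robust to outlying genes, over 5542 genes with a mean of at least 1 TPM, leaving out the libraries of low recovery. The test planned for total RNA needed counts as deposited. Since the values are scaled, the fallback named in the plan, limma on log2(value + 1), was the main test, over 4019 features that pass edgeR's expression filter on the recovered reads. The edgeR 4.0.16 quasi-likelihood test on those reads was added after the files were seen, and log2(value + 1) replaced log2 CPM in the correlations, list tests and interaction. The 44 features of the rDNA were left out of this test. Slopes are log2 units per 100 repeats, which understate changes of low genes, and p-values are two-sided with Benjamini-Hochberg adjustment at 0.05. The limma p of a single gene planned for its own test (SIR2) is given unadjusted too. The limma and permutation p measure the spread between strains with 1 library each, while camera at the preset correlation holds little of it.

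Gene symbols and coordinates come from the reference annotation of the S288C genome, which matched 5817 polyA and 6052 total RNA identifiers; the deposited tables hold no coordinates. Of 41 gene lists, those with at least 3 measured members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The genes named are those past the threshold, up to 12 per direction, or else the 6 with the lowest p in each direction, leaving out frames with no symbol. To these are added all measured members of the Sir silencing complex, of the RNA polymerase I initiation factors and of the deleted loci, FOB1, the 4 members with the lowest p of each list past its test, and up to 2 of each other list. Correlations with repeat number used permutation tests with 100000 resamples (exact below 10 strains) in Python 3.11.15 with scipy 1.17.1, and exact permutations inside strain series. The interaction of assay and repeat number was fitted over 3662 genes measured in both assays. Both libraries of a strain come from the same strain, so they are paired: deviations of the same strain correlated at 0.14 to 0.52 across assays, over 0.1 in 10 of 10 pairs. The fit with strain as a block called 0 genes, as did the fit without it. Chromosome medians were compared with the median library of each assay.

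The fits were tested on simulated data with 200 changed genes. Of slopes of 0.25, 0.5 and 1 per 100 repeats, limma recovered 29.9%, 82.1% and 98.5% among 5542 polyA genes, and 0%, 22.4% and 74.2% among 4019 total RNA features. The interaction fit recovered 1.49%, 17.9% and 81.8% among 3662 genes. In the polyA, total RNA and interaction simulations 4, 5 and 8 unchanged genes were called. The simulated noise was independent between genes, while genes of the real libraries vary together, so the shares may be too high for them. Alternatives covered the pseudocount, filters, scaling, library sizes, the scale of array length, strain series, other tools and leaving out each strain. The same fits were repeated for 100 assignments of the repeat numbers to the strains, the real one included.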

Results

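RNA was sequenced from haploid MATa strains of budding yeast (Saccharomyces cerevisiae) of one genotype that differ in the length of the ribosomal DNA (rDNA) array, the tandem block of rRNA genes on chromosome XII. The labels give each strain its repeat number. Strains with 72, 84, 118, 129, 147, 156, 197, 208, 224 and 237 repeats each had 1 library of polyA-selected RNA and 1 library of total RNA. A further 2 strains, with 104 and 166 repeats, had only polyA libraries that the labels mark as low in polyA recovery, and they entered slope fits only as alternatives. Each array length was 1 strain with 1 library per assay, so each comparison is a slope over 10 strains and its error is the spread between strains, which holds any other difference between them. Strain names fall into 4 series, and among the 10 strains the 3 of series CGY28 have long arrays (197, 208 and 224 repeats), its other strain being that of low recovery with 166 repeats, while series CGY29 has 1 strain. The polyA values are TPM, transcript abundances scaled to the same sum in each library, and keep no depth. Summed over all listed features, the total RNA libraries held 6495626 to 7934346 reads, of which 377986 to 465645 fell outside the rDNA. If a read was counted at each identical copy, as in the rDNA, these sums exceed the number of reads sequenced. The median tested feature had 26.1 reads per library.

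The first gene asked about was SIR2, which encodes the histone deacetylase that silences chromatin at the rDNA. In polyA RNA the SIR2 transcript (YDL042C, protein-coding, chromosome IV, 376757 to 378445) rose with repeat number. It stood at 11.05 and 9.81 TPM in the strains with 72 and 84 repeats and at 19.0 and 19.8 TPM in those with 224 and 237 repeats, with a mean of 15.9 ± 3.64 TPM (SD, n = 10). The slope was 0.47 ± 0.10 (SE) on the log2(TPM + 1) scale per 100 repeats, with a 95% confidence interval of 0.25 to 0.69 and an unadjusted limma p of 0.000461. The other members of the Sir silencing complex had slopes of -0.08 ± 0.10 for SIR4, -0.06 ± 0.10 for SIR3 and -0.05 ± 0.10 for SIR1, with means of 8.53, 6.63 and 5.81 TPM.

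Across the 10 strains the log2 value of SIR2 in polyA RNA correlated with repeat number with Pearson's r = 0.81 (permutation p = 0.00420) and Spearman's rho = 0.78 (permutation p = 0.0104). Adjusted over the 3 relations tested in this family, these were 0.0126 and 0.0313. Without the strains with 72 and 237 repeats, the farthest from the median array length, r was 0.71 (exact permutation p = 0.0398). Within strain series r was 0.70, and an exact permutation of strains inside their series gave p = 0.130 over 216 arrangements. Taken over all 5542 genes, SIR2 did not pass: its limma adjusted p was 0.483, and it was the 1 of 4 Sir complex members to pass adjusted over the list alone. The strains with low polyA recovery had 13.2 TPM (104 repeats) and 16.0 TPM (166 repeats).

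**Figure D1:**
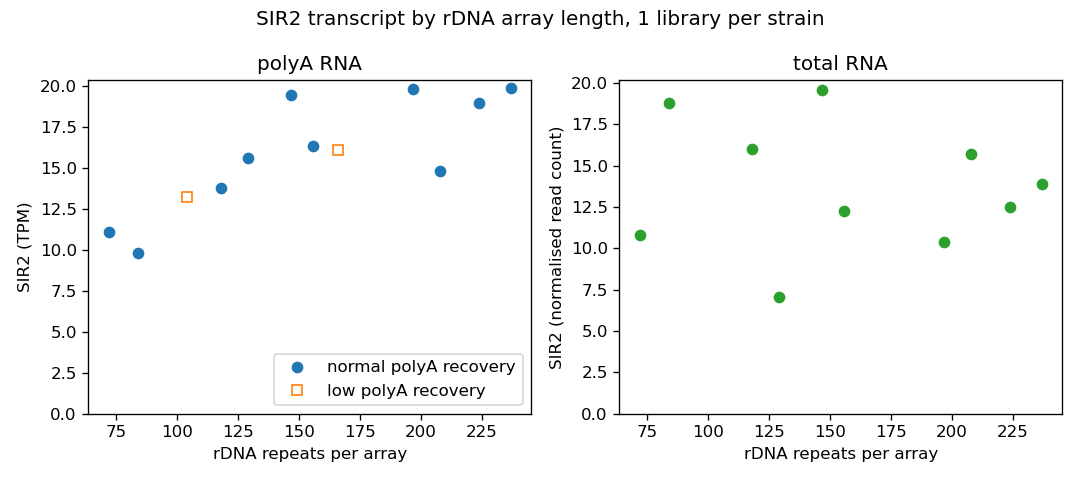
SIR2 transcript level against rDNA repeats per array, in TPM for polyA RNA (left; circles, 10 strains of normal polyA recovery; open squares, 2 strains of low recovery) and in normalised read counts for total RNA (right, 10 strains); each point is 1 library. The polyA values run from 9.81 to 19.8 TPM and the total RNA values from 7.06 to 19.6.

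Over the whole polyA transcriptome no gene passed an adjusted p of 0.05: 0 of 5542 genes were called by limma, with a lowest adjusted p of 0.326. At an unadjusted p under 0.05 there were 312 genes, 108 with a positive and 204 with a negative slope. The split was 160 positive and 153 negative without the strain with 208 repeats, 172 and 199 with TMM factors, 220 and 198 with quantile normalisation, and 61 and 45 with strain series as a covariate. For independent genes 277.1 would be expected by chance, but these genes vary together. Random assignments of the repeat numbers gave a median of 177, and 29 of 100, the real one included, gave at least 312. The lowest p with a positive slope belonged to FIT2, a cell wall mannoprotein of siderophore iron uptake (0.41 ± 0.08 per 100 repeats), LDO45, a lipid droplet protein (0.34 ± 0.07), SIR2, THI4, of thiamine biosynthesis (0.45 ± 0.11), STE3, the a-factor receptor (0.38 ± 0.10, at a mean of 3.48 TPM), and STE2, the alpha-factor receptor (0.18 ± 0.05, at 419.3 TPM). With a negative slope they were COX17, a copper chaperone for cytochrome c oxidase (-0.30 ± 0.07), CBP4, an assembly factor of the cytochrome bc1 complex (-0.29 ± 0.07), RTC3 (-0.53 ± 0.13), ATP23, a mitochondrial protease (-0.39 ± 0.10), MRPL31, of the mitochondrial ribosome (-0.34 ± 0.09), and GCV1, of the glycine cleavage complex (-0.28 ± 0.07). None of these passed, with limma adjusted p of 0.326 for FIT2 and LDO45 and 0.483 for the other named genes. Without the strain with 197 repeats the unnamed frame YGL258W-A was called, and without the strain with 237 repeats YIR020C; both were named only after their values were seen. With strain series as a covariate 0 genes were called and 106 had an unadjusted p under 0.05.

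Gene groups fixed beforehand moved by small amounts. The median slope over all 5542 polyA genes was -0.02, and the counts of signs and the list medians do not take that tilt out. Transcripts of mitochondrial ribosomal proteins fell, with a negative slope for 54 of 56 measured members and a median of -0.13 per 100 repeats (camera adjusted p = 3.18e-14), while amino acid biosynthesis genes rose, with a positive slope for 41 of 45 members and a median of 0.07 (camera adjusted p = 5.95e-11). With an estimated correlation between genes in place of the preset one, neither list passed (adjusted p = 0.375 with an estimated correlation for each). MRPL31, MRPL38 (-0.32 ± 0.08) and MRP35 (-0.34 ± 0.09) lead the first list, of which 17 members had an unadjusted p under 0.05, 0 passed over all genes tested and 3 passed adjusted over the list alone. MRPL50 had -0.29 ± 0.09. In the second list ARO4 (0.13 ± 0.05), LYS1 (0.11 ± 0.04), LYS2 (0.14 ± 0.06) and HOM2 (0.09 ± 0.04) had the lowest p, and 0 members passed over all genes or adjusted over the list alone. With strain series as a covariate the median of the first list was -0.07 and that of the second 0.04 (camera adjusted p = 0.146). With a trend on coding length and abundance removed from each library, the medians were -0.08 and 0.04.

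The a-specific genes, which MATa cells express for mating, rose: all 7 measured members had positive slopes, with a median of 0.17 per 100 repeats (camera adjusted p = 4.02e-07; adjusted p = 0.375 with an estimated correlation). STE2, ASG7 (0.39 ± 0.15), BAR1 (0.12 ± 0.06), which encodes the protease that degrades alpha-factor, and MFA2 (0.15 ± 0.07), an a-factor gene at a mean of 8183 TPM, had the lowest p. In this list 3 members had an unadjusted p under 0.05, 0 passed over all genes and 1 passed adjusted over the list alone. Haploid-specific genes had a median slope of 0.00 over 14 members, 7 of them positive (camera adjusted p = 0.792). That median was 0.10 with strain series as a covariate (camera adjusted p = 0.0359). DDR48 (-0.19 ± 0.06) and HO (-0.15 ± 0.08) had the lowest p in that list. The a-specific median was 0.22 with strain series as a covariate and 0.10 without the strain with 208 repeats.

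Glycolytic genes rose as well, 16 of 20 with a positive slope and a median of 0.08 (camera adjusted p = 1.51e-08; adjusted p = 0.410 with an estimated correlation). TDH2, a glyceraldehyde-3-phosphate dehydrogenase gene, had 0.21 ± 0.06 per 100 repeats, FBA1 0.11 ± 0.04, CDC19 0.12 ± 0.04 and ENO1 0.22 ± 0.08, and of the list 0 members passed over all genes and 1 adjusted over the list alone. The glycolytic median was 0.14 with strain series as a covariate and 0.05 with the trend on coding length and abundance removed. Proteasome genes fell, 31 of 32 with a negative slope and a median of -0.09 (camera adjusted p = 6.84e-06; adjusted p = 0.639 with an estimated correlation), as PRE10 (-0.14 ± 0.06), PUP3 (-0.13 ± 0.06), PRE6 (-0.11 ± 0.05) and RPN10 (-0.11 ± 0.05) illustrate. Ribosome biogenesis genes fell, 67 of 74 with a negative slope and a median of -0.08 (camera adjusted p = 3.19e-05; adjusted p = 0.754 with an estimated correlation). Their lowest p belonged to IMP3 (-0.29 ± 0.08), RLP7 (-0.20 ± 0.08), IMP4 (-0.20 ± 0.09) and RPF2 (-0.18 ± 0.08). The medians of the proteasome and ribosome biogenesis lists were -0.05 and -0.03 both with strain series as a covariate and without the strain with 208 repeats. That of ribosome biogenesis was -0.13 without the strain with 237 repeats and -0.05 with quantile normalisation. Histone genes fell, 10 of 11 with a negative slope and a median of -0.09 (camera adjusted p = 0.00181; adjusted p = 0.393 with an estimated correlation), with HTA2 at -0.19 ± 0.06, HHT2 at -0.11 ± 0.05, HHT1 at -0.17 ± 0.07 and HHF1 at -0.14 ± 0.06, and the list had a median of -0.05 and a camera adjusted p of 0.0514 with strain series as a covariate. Its median was -0.15 without the strain with 237 repeats. General stress genes had a negative slope in 27 of 36 members and a median of -0.10 (camera adjusted p = 0.00853; adjusted p = 0.674 with an estimated correlation). CTT1, the cytosolic catalase, had -0.35 ± 0.11, SSA4 -0.28 ± 0.10, HSP42 -0.27 ± 0.10 and GAD1 -0.25 ± 0.11. The stress median turned to 0.07 with strain series as a covariate (camera adjusted p = 0.455), and without the strain with 84 repeats it was -0.06 and the list no longer passed (camera adjusted p = 0.448). It was -0.16 without the strain with 237 repeats.

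Genes within 20 kb of a chromosome end rose, 113 of 175 with a positive slope and a median of 0.04 (camera adjusted p = 0.000114; adjusted p = 0.424 with an estimated correlation). The median was 0.07 both without the strain with 208 repeats and with strain series as a covariate, and 0.02 without the strain with 197 or 224 repeats. Among them were SEO1 (0.54 ± 0.14, at a mean of 1.31 TPM), the unnamed frames YER187W (0.56 ± 0.15) and YGL258W-A (0.99 ± 0.27), and MAN2 (0.38 ± 0.12). The COS list was taken by symbol alone, so membership of the subtelomeric COS family was not checked for each gene, COS111 included. It had a positive slope in 11 of 11 members and a median of 0.08 (camera adjusted p = 0.0189, or 0.460 with an estimated correlation). COS111 had 0.17 ± 0.11, COS12 0.27 ± 0.24, COS7 0.08 ± 0.08 and COS10 0.10 ± 0.10. In total RNA 3 measured members of the list had a positive and 3 a negative slope, with a median of 0.16 (camera adjusted p = 0.924). Several members of this list are similar in sequence, so the split of reads between them is uncertain. NAD metabolism genes had a positive slope in 13 of 17 members and a median of 0.07 (camera adjusted p = 0.00428; adjusted p = 0.375 with an estimated correlation), among them BNA4 (0.22 ± 0.09), BNA6 (0.13 ± 0.05) and QNS1 (0.09 ± 0.06), with NRK1 at -0.23 ± 0.13. Methionine and sulfate assimilation had a median of 0.04 over 22 members (camera adjusted p = 0.0349; adjusted p = 0.389 with an estimated correlation), with MMP1 at 0.20 ± 0.09, CYS3 at 0.09 ± 0.05, MET13 at 0.11 ± 0.07 and MET17 at 0.08 ± 0.05. Oxidative phosphorylation had a median of 0.02 over 39 members (camera adjusted p = 0.0405; adjusted p = 0.674 with an estimated correlation), with QCR10 at 0.26 ± 0.07, SDH2 at 0.16 ± 0.06, ATP19 at -0.17 ± 0.07 and RIP1 at 0.11 ± 0.05. Its median was -0.01 with strain series as a covariate. The COS, oxidative phosphorylation and methionine lists no longer passed in 2, 4 and 4 of the 10 fits that each left out 1 strain, the strains with 72 and 208 repeats among them in each case. With strain series as a covariate the COS, NAD, methionine and oxidative phosphorylation lists did not pass either (camera adjusted p = 0.154, 0.134, 0.0593 and 0.109), with medians of 0.04 for the COS and 0.09 for the methionine list. The methionine and oxidative phosphorylation lists did not pass with quantile normalisation either (camera adjusted p = 0.0992 and 0.159). The methionine list did not pass with the trend on coding length and abundance removed (camera adjusted p = 0.246). The oxidative phosphorylation median was 0.05 there. In the fit without the strain with 224 repeats the medians were 0.04 for the COS and 0.04 for the NAD list. They were 0.02 for the methionine and 0.000174 for the oxidative phosphorylation list. The COS median was 0.05 without the strain with 208 repeats, and the methionine median 0.01 without that with 237. That of oxidative phosphorylation was 0.01, 0.04 and 0.04 without the strain with 72, 84 or 237 repeats.

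In all, 13 of 36 lists with at least 3 measured members passed camera with the preset correlation in polyA RNA, 0 with an estimated correlation and 0 by fry. Several lists tied to the rDNA did not pass. RNA polymerase I initiation factors had a median slope of -0.05 over 10 members (camera adjusted p = 0.792), from -0.17 ± 0.11 for RRN11 to 0.10 ± 0.06 for HMO1, with -0.14 ± 0.13 for RRN10, -0.07 ± 0.07 for RRN7, -0.06 ± 0.11 for UAF30, -0.06 ± 0.09 for RRN6, -0.05 ± 0.10 for RRN9, -0.02 ± 0.08 for SPT15, -0.00 ± 0.09 for RRN3 and 0.01 ± 0.08 for RRN5. FOB1, which encodes the replication fork barrier protein of the rDNA, had -0.11 ± 0.10. Cytosolic ribosomal protein genes had a median of -0.03 over 138 members against a camera test in the positive direction (adjusted p = 0.884), and the genes that flank the rDNA a median of -0.08 over 11 (camera adjusted p = 0.609). The Sir list had a median of -0.06 and a mean of 0.07, since SIR2 alone was positive, and a camera test in the positive direction (adjusted p = 0.364). As signs of other cell types, meiosis and sporulation genes had a median of 0.07 over 11 members (camera adjusted p = 0.0537) and alpha-specific and silent cassette genes a median of -0.09 and a mean of 0.04 over 6 (camera adjusted p = 0.981), of which 1, STE3, passed adjusted over the list alone.

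**Figure D2:**
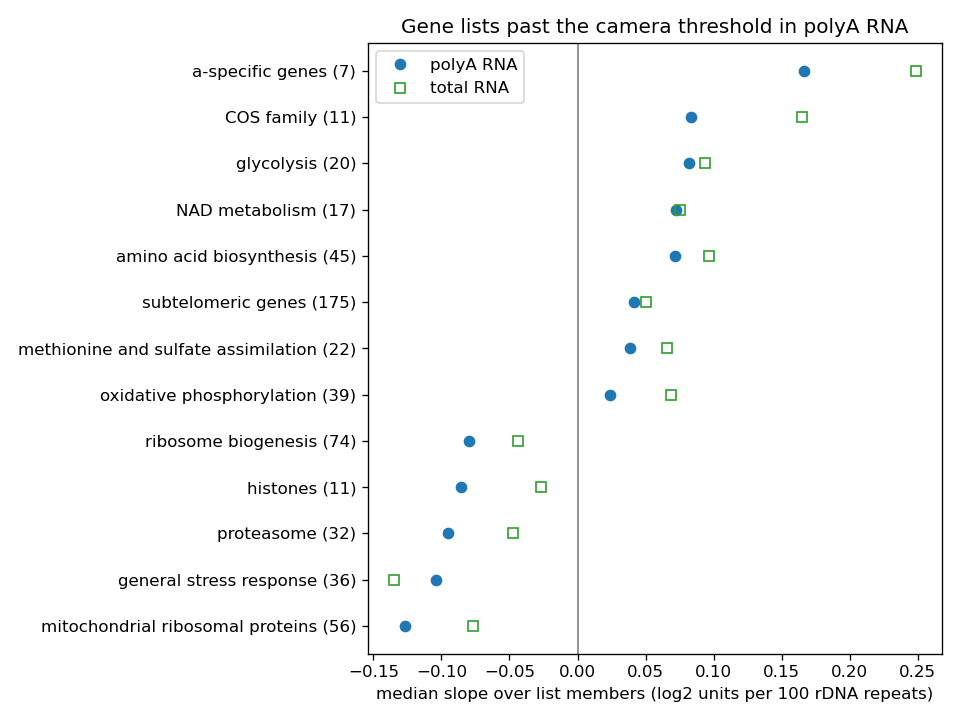
Median slope of each gene list past the camera threshold in polyA RNA, in log2 units per 100 rDNA repeats, for polyA RNA (circles) and total RNA (open squares); the number of members measured in polyA RNA follows each name. In polyA RNA the medians run from -0.13 for mitochondrial ribosomal proteins to 0.17 for a-specific genes.

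The same 10 strains were compared in total RNA, where transcripts without a polyA tail are kept. A single feature was called by limma among 4019: YDR154C, a reading frame with no gene symbol, chosen for mention after its values were seen, which rose from 30.6 normalised counts at 72 repeats to 98.1 at 237 (slope 0.72 ± 0.13 per 100 repeats, limma adjusted p = 0.0132). CPR1, a cyclophilin gene whose systematic name follows directly, had a slope of 0.04 ± 0.07. Without the strain with 72 repeats the slope of YDR154C was 0.51 (limma adjusted p = 0.915), and without the strain with 237 repeats 0.73 (limma adjusted p = 0.0541). In the latter fit limma called the Ty frames YPR158C-C and YER160C, likewise named after their values were seen. With strain series as a covariate limma called 0 features (lowest adjusted p = 0.124, 149 at an unadjusted p under 0.05). At an unadjusted p under 0.05 there were 188 features, where 200.95 would be expected by chance for independent features. Random assignments of the repeat numbers gave a median of 173, and 34 of 100, the real one included, gave at least 188. The edgeR quasi-likelihood test on reads recovered from the deposited values called 3 features, namely YDR154C (0.69, edgeR adjusted p = 0.0170), the Ty frame YOR192C-A (1.64, edgeR adjusted p = 0.0180) and LSR1, the U2 spliceosomal RNA (-1.84, edgeR adjusted p = 0.0252). By limma the adjusted p was 0.114 for YOR192C-A and 0.987 for LSR1. The Ty frame YOR192C-B, whose span holds that of YOR192C-A, had a slope of -0.24, so the split of reads between these frames is uncertain. YOR192C-A, YOR192C-B and LSR1 were named after their values were seen. The feature LSR1 held a mean of 7.04 normalised counts, while the exon feature of the same RNA held 2076 and had a slope of -0.10 ± 0.06, so reads of this RNA are split between features.

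The genes with the lowest p and a positive slope in total RNA were TDH2 (0.23 ± 0.07), MFA1, an a-factor gene (0.32 ± 0.10), the triacylglycerol lipase gene TGL5 (0.56 ± 0.18), TUL1 (0.59 ± 0.19), TEF4, a translation elongation factor gene (0.20 ± 0.06), and LPX1, a peroxisomal lipase gene (1.09 ± 0.36). With a negative slope they were RPN7 (-0.48 ± 0.14) and RPN8 (-0.53 ± 0.16), of the proteasome, PEX19 (-0.85 ± 0.26), CPP2 (-0.64 ± 0.21), SIT1, a siderophore transporter gene (-0.76 ± 0.25), and PET309 (-0.86 ± 0.29). Each had a limma adjusted p of 0.987. SIR2 had a slope of -0.02 ± 0.24 (limma p = 0.948) on 7 to 21 reads per library, with a confidence interval of -0.51 to 0.48. Its r with repeat number was -0.02 (permutation p = 0.951) and its rho -0.05 (permutation p = 0.893), or 0.951 and 0.893 adjusted over the 3 relations, with r = -0.22 without the strains with 72 and 237 repeats (exact permutation p = 0.606) and -0.20 within series (exact permutation p = 0.644). That interval takes in the polyA slope, so a difference was not detectable at this depth. SIR3 had -0.16 ± 0.24, SIR4 -0.20 ± 0.16 and FOB1 -0.27 ± 0.26. Initiation factors of RNA polymerase I lay between -0.17 ± 0.19 for RRN3 and 0.19 ± 0.19 for RRN6, with HMO1 at 0.17 ± 0.14, RRN7 at 0.09 ± 0.24, SPT15 at 0.03 ± 0.19, RRN11 at -0.06 ± 0.34, RRN9 at -0.07 ± 0.31 and RRN5 at -0.14 ± 0.32.

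In total RNA 5 of 36 lists passed camera with the preset correlation, and 0 with an estimated correlation or by fry. The a-specific genes rose, 6 of 6 members with a positive slope and a median of 0.25 per 100 repeats (camera adjusted p = 0.000125; adjusted p = 0.626 with an estimated correlation). MFA1, MFA2 (0.31 ± 0.11), STE2 (0.19 ± 0.09) and AGA2 (0.31 ± 0.20) had the lowest p, and 2 members passed adjusted over the list alone. Amino acid biosynthesis genes rose, 39 of 44 with a positive slope and a median of 0.10 (camera adjusted p = 8.09e-05; adjusted p = 0.626 with an estimated correlation), among them GCN4, which encodes the activator of the pathway (0.21 ± 0.08), LYS1 (0.19 ± 0.09) and ILV6 (0.17 ± 0.09), with HIS7 at -0.34 ± 0.17. Without the strain with 224 repeats this list had a median of 0.06 and a camera adjusted p of 0.0623, and with strain series as a covariate its median was -0.01 (camera adjusted p = 0.746). Glycolysis had a positive slope in 15 of 20 members and a median of 0.09 (camera adjusted p = 0.00101; adjusted p = 0.626 with an estimated correlation), with TDH2, ENO1 (0.24 ± 0.10), ENO2 (0.11 ± 0.05) and PGI1 (0.14 ± 0.07) first. General stress genes had a median of -0.13 over 20 members and ribosome biogenesis genes -0.04 over 74 (camera adjusted p = 0.0319 for each; adjusted p = 0.626 with an estimated correlation). In the former YGP1 had -0.64 ± 0.30, HSP12 -0.84 ± 0.49, GAD1 -0.42 ± 0.28 and HSP104 -0.16 ± 0.11, and in the latter BFR2 had -0.55 ± 0.19, UTP21 -0.36 ± 0.14, KRR1 -0.43 ± 0.19 and UTP7 -0.38 ± 0.18. Those 2 lists no longer passed in 3 and 4 of the fits that left out 1 strain, nor with strain series as a covariate (medians of -0.03 and -0.02, camera adjusted p = 0.911 and 0.766). The glycolytic median was 0.06 without the strain with 208 repeats (camera adjusted p = 0.0478). That of ribosome biogenesis was -0.01 in the same fit (camera adjusted p = 0.758). The ribosome biogenesis median was -0.07 and -0.08 without the strain with 84 or 237 repeats, and the stress median -0.06 and -0.05 without that with 72 or 84. Mitochondrial ribosomal protein genes did not pass in total RNA: 16 of 26 members had a negative slope, with a median of -0.08 (camera adjusted p = 0.429), or 0.00420 with strain series as a covariate (camera adjusted p = 0.773).

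Whether longer arrays come with more rRNA was asked of the total RNA libraries. With all listed rDNA copies summed, nuclear rRNA took 92.6 ± 0.459% of reads (SD, n = 10). It ran from 91.8% in the strain with 147 repeats to 93.3% in the strain with 84. With 1 genomic copy of each rRNA counted, the shares in these strains were 84.8% and 87.4%, so the level depends on how copies are counted. The share over all copies did not change detectably with array length: r was -0.52 (permutation p = 0.123) and rho -0.53 (permutation p = 0.124), or 0.184 and 0.186 adjusted over the 3 relations of the family. With 1 genomic copy of each rRNA counted r was -0.53 (permutation p = 0.119). With reading frames inside the rDNA counted as rRNA r was -0.05 (permutation p = 0.914), and without the strain with 147 repeats it was -0.69 (exact permutation p = 0.0442). Without the strains with 72 and 237 repeats r was -0.42 (exact permutation p = 0.303), and within strain series it was -0.56 (exact permutation p = 0.315). With all copies summed, as for the other species, the 25S rRNA took 54.7 ± 0.872% of reads and the 18S rRNA 36.1 ± 0.805%. The 5.8S rRNA took 0.724 ± 0.228%, the 5S rRNA 0.0694 ± 0.0405% and the 35S precursor with its spacers 0.938 ± 0.0754%. For these species r with repeat number was -0.48, 0.17, 0.23, 0.26 and -0.20 in that order, rho -0.33, 0.10, -0.01, 0.08 and -0.14, with permutation p of 0.158, 0.642, 0.573, 0.503 and 0.586 for r, and 0.348, 0.785, 1, 0.837 and 0.707 for rho. Adjusted over the 5 relations of this family the p for r was 0.642 and that for rho 1 in every case. Without the strains with 72 and 237 repeats r was -0.39, 0.02, 0.35, 0.40 and -0.54, and within series -0.25, -0.01, -0.10, -0.22 and 0.23. The strain with 208 repeats had the highest 5.8S and 5S shares. With it left out r was -0.39, 0.01, -0.10, -0.01 and -0.10. Reads here are shares of a library, so they carry no measure of rRNA per cell.

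**Figure D3:**
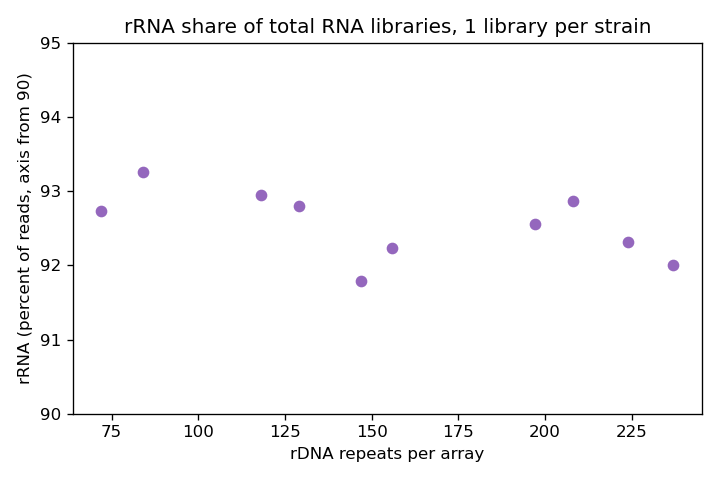
Nuclear rRNA as a percent of all reads in each total RNA library against rDNA repeats per array; each of the 10 points is 1 strain, and the vertical axis starts at 90. With all listed copies summed, as drawn, the share lies between 91.8% and 93.3%.

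Whether a gene's slope depends on the assay was tested over the 20 libraries of the 10 strains. No gene passed: limma called 0 of 3662 genes for the interaction of assay and repeat number, with 120 at an unadjusted p under 0.05. For SIR2 the slope in polyA RNA minus that in total RNA was 0.49 ± 0.26 (unadjusted limma p = 0.0773), so the SIR2 slopes of the assays were not shown to differ. Across genes, which are not independent replicates, the slopes of the assays correlated with r = 0.25 and rho = 0.27, and 62.1% of genes had the same sign. Repeat numbers assigned to the strains at random, jointly in both assays, gave a median r of 0.22 and a range of 0.05 to 0.42, which takes in the observed r.

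The genotype of the labels carries deletions at HIS3, LYP1 and CAN1. LYP1, a lysine permease gene, was listed at 0 TPM in all 12 polyA libraries and had 0 or 1 read in total RNA. CAN1, the arginine permease gene whose locus carries the STE2 promoter cassette, was listed at 0 TPM in all 12 polyA libraries and had 24 to 36 reads in each total RNA library. Those reads go against a loss of the whole gene, and whether both assays were counted on the same transcript set is not given in the sources used here, so the value of 0 TPM does not check the label. HIS3 was read at 86.0 to 103 TPM, which checks nothing, since the deposited values do not tell which part of the gene was read. No strain had a chromosome whose median departed by more than 0.3 (log2) in both assays: the farthest medians were -0.17 for chromosome XV in polyA RNA and 0.06 for chromosome III in total RNA, both in the strain with 208 repeats. That strain stood apart in polyA RNA, where its median gene lay at -0.15 (log2) against the median library. It was first on the leading principal component of both assays (22.0 in polyA RNA and 24.4 in total RNA).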

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

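Planned were the fits without 1 strain for SIR2, those with strain series as a covariate and the counts of random assignments for the list medians, the fits being read as tests of an explanation only after the data were seen, when all other tests here were chosen.

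SIR2 rose with repeat number in polyA RNA. No slope was detected in total RNA, though the slopes of the assays were not shown to differ. Dependence on 1 strain is argued against, since the highest limma p over the 10 fits that each leave out 1 strain was 0.00373. Strain series as the whole cause is argued against by limma with series as a covariate (slope 0.42, p = 0.0248), though an exact permutation inside series did not pass (r = 0.70, p = 0.130), so a part played by series stays open. The missing slope in total RNA may come from depth alone: on 7 to 21 reads the upper bound of its interval was 0.48, above the polyA slope of 0.47. That array length itself raises SIR2 transcript remains an open hypothesis, since each array length is 1 strain.

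Mitochondrial ribosomal protein transcripts fell in polyA RNA. Coding length alone is argued against: slopes correlated with coding length across 5536 polyA genes (rho = 0.20), but after removal of that trend and of the trend on abundance, the mean of the list per strain still correlated with repeat number (r = -0.81, permutation p = 0.00365), while the median slope shrank from -0.13 to -0.08. The strain with 208 repeats alone is argued against as well (r = -0.81 without it, exact permutation p = 0.00651). Strain series may account for it, since within series r was -0.37 (exact permutation p = 0.153), although the list passed camera with series as a covariate (median -0.07, adjusted p = 6.79e-06), a test that at a preset correlation holds little of the spread between strains. Chance could not be excluded, because 5 of 100 assignments of repeat numbers gave a median as large as the real -0.13, with a highest other of -0.14. The correlations of the list mean do not allow for the choice of this list out of 36 after it had passed camera.

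The a-specific genes rose in both assays. Of 100 assignments 3 gave a polyA median as large as 0.17 (highest other 0.21), which excludes chance only for a list named in advance; this one was picked out of 36 after its result was seen, so chance stays open, and without the strain with 208 repeats the median was 0.10. Scaling is argued against by the median slope, which was 0.15 with quantile normalisation and 0.19 with TMM factors. The list still passed camera with quantile normalisation (camera adjusted p = 3.16e-05). That p adds little, since camera sets a list against the other genes of the same libraries. Strain series stays open. With series as a covariate the list passed camera in polyA RNA (median 0.22, adjusted p = 4.19e-08) and total RNA (0.21, adjusted p = 0.00143). The mean per strain in polyA RNA did not pass within series (r = 0.76, exact permutation p = 0.0926). In the main fits the list did not pass camera with an estimated correlation (adjusted p = 0.375 in polyA RNA and 0.626 in total RNA). Leaky silent mating cassettes in short arrays would lower haploid-specific genes too and may play a part. The a-specific mean less the haploid-specific mean per strain correlated with repeat number (r = 0.64, permutation p = 0.0331) but did not pass within series (r = 0.50, exact permutation p = 0.106). HMLALPHA2 had a slope of -0.26 (95% interval -0.56 to 0.03), but this cannot be read as cassette expression. Its values equal those of its copy MATALPHA2, and HMRA2 ran from 0.00265 to 16.9 TPM, so the locus its reads came from is not known. Other values do not settle it. Alpha-specific STE3 had a slope of 0.38 (limma p = 0.00154), but at a mean of 3.48 TPM and as the member of its list with the lowest p. HMLALPHA1 was listed at no more than 0.135 TPM, near the floor. The haploid-specific mean had r = -0.06 over all strains (permutation p = 0.877) and 0.48 within series (exact permutation p = 0.236).

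Of 135 values tested for a strain far from the other strains, 11 were found, and 10 of the 11 are the strain with 208 repeats. Chance gives about 1 in 20 for independent values. Here 121 of the 135 were gene values from the same libraries, and a leading principal component is built to spread widely. The flags are thus not independent, and their number is no test against chance. The ratios are the gap to the next strain over the whole range. In total RNA they were 0.488 for the share of 5.8S rRNA (1.29% against a next highest of 0.931%), 0.517 for 5S rRNA (0.169% against 0.0934%), 0.484 for the leading principal component and 0.472 for PGI1 (1142 normalised counts against 982.4). In polyA RNA they were 0.599 for the leading principal component, 0.477 for SIR4 (lowest, 6.24 TPM), 0.632 for RRN6 (lowest, 8.19 TPM), 0.502 for RLP7 (lowest, 71.4 TPM), 0.474 for HHT1 (lowest, 730.9 TPM) and 0.646 for COS12 (highest, 12.4 TPM). The remaining one was SDH2, highest in the strain with 224 repeats (54.9 TPM, ratio 0.476).

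Reads were found in rDNA spacers, which no planned comparison used. The NTS2 spacer held up to 180 reads, in the strain with 147 repeats, and as few as 4 in the strain with 208. The NTS1 spacer held at most 8 reads, in the strain with 197 repeats.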

How the results depend on the processing

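Chosen after the data were seen were edgeR on recovered reads, 2 other ways to count rRNA, the list tests with quantile scaling or with the length trend removed, and leaving out strains in the list, agreement and interaction tests. The SIR2 slope in polyA RNA kept its direction and its side of p = 0.05 in 22 of 22 alternatives, at 0.37 to 0.51, or 0.38 to 0.53 with 1 strain left out. The first range mixes units, in total RNA too. It holds the difference between the 5 longest and 5 shortest arrays (0.37 in polyA RNA) and the slope per unit of log2 repeats (0.49). The correlation of SIR2 within series is not among the 22 alternatives and did not pass (exact permutation p = 0.130). In total RNA the SIR2 slope ran from -0.13 to -0.02, and from -0.14 to 0.14 with 1 strain left out, never past the threshold. With at least 50 counts it was not tested. The polyA count of calls by limma stayed at 0 in all 12 alternative fits and was 0 to 1 with 1 strain left out. The total RNA count of 1 became 3 by edgeR on recovered reads (186 features at an unadjusted p under 0.05). In edgeR it was also 3 with DESeq2 size factors and 3 with rRNA kept in, so neither choice moved the edgeR count. The count was 2 by DESeq2. By limma it was 4 with no filter, 0 with strain series as a covariate (149 features), and 0 to 2 with 1 strain left out. The cause was not tested. The interaction count was 0 with the higher filter and with the strain as a replicate block (175 genes at an unadjusted p under 0.05), and 0 to 1 with 1 strain left out (1 without the strain with 224 repeats). The block changed no call. List counts fell from 13 and 5 to 0 with an estimated correlation and 0 by fry, and were 11 to 16 in polyA RNA and 2 to 7 in total RNA with 1 strain left out (2 without the strain with 224 repeats). The slope agreement ran from 0.16, without the strain with 208 repeats, to 0.33. The rRNA share had r of -0.69 to -0.37 with 1 strain left out, past the threshold only without the strain with 147 repeats (exact permutation p = 0.0442), and -0.05 with reading frames inside the rDNA counted. No chromosome was outlying at 0.3 or 0.5, so leaving out such libraries was not run. TMM and quantile scaling moved the median polyA slope by 0.02, and 3 list medians changed sign, none of a list past the threshold. At the depth and spread of the total RNA libraries 22.4% of simulated slopes of 0.5 were recovered among 4019 features; depth was not varied by itself.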

Other observations

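Chosen after the values were seen were the counts of random assignments for calls of single genes, the tests on spacer reads and those on list means per strain.

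The iron regulon held FIT2, the gene with the lowest polyA p, yet its median slope was -0.00 over 23 members (camera adjusted p = 0.364, while with TMM or quantile scaling the median was 0.02), with FRE4 at 0.21 ± 0.12, and 1 member passed adjusted over the list alone. Of seripauperin genes, PAU5 had -0.57 ± 0.18 and PAU7 -1.35 ± 0.57, and the list had a median of 0.05 and a mean of -0.13 (camera adjusted p = 0.854). IME1, which encodes the activator of meiosis, had 0.41 ± 0.13 at a mean of 5.70 TPM. None of these genes passed limma's adjusted p, at 0.326 for FIT2 and 0.751 or more for the rest. In total RNA, which keeps unpolyadenylated transcripts, Ty frames had a median slope of -0.01 over 75 members (camera adjusted p = 0.866), small nucleolar and other stable noncoding RNAs -0.04 over 54 (camera adjusted p = 0.0690) and mitochondrially encoded genes -0.05 over 7 (camera adjusted p = 0.727). YRF1-2, a helicase gene of the telomeric Y prime element, had 0.41 ± 0.16.

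The mean log2 value of the a-specific genes per strain correlated with repeat number in polyA RNA (r = 0.66, permutation p = 0.0424; rho = 0.66, p = 0.0444) and in total RNA (r = 0.70, permutation p = 0.0282; rho = 0.71, p = 0.0275). That of the mitochondrial ribosomal protein genes in polyA RNA had r = -0.71 (permutation p = 0.0134) and rho = -0.92 (permutation p = 0.000620). Adjusted over the 3 relations the p for r was 0.0424, 0.0424 and 0.0402, and that for rho 0.0444, 0.0413 and 0.00186. These lists were taken up after they had passed camera among 36 lists in the same strains. The adjustment over 3 relations does not allow for that choice. Without the strains with 72 and 237 repeats r was 0.48, 0.57 and -0.85, and the relations of the a-specific genes no longer passed over the 8 strains left (exact permutation p = 0.231 and 0.142, against 0.00469 for the third). They did not pass without the strain with 208 repeats either (r = 0.62 and 0.67, exact permutation p = 0.0789 and 0.0513). Within series r was 0.76, 0.72 and -0.37 (exact permutation p = 0.0926, 0.0972 and 0.153).

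The NTS2 spacer of the rDNA ran from 3.92 to 176 normalised counts with r = 0.37 (permutation p = 0.302) and rho = 0.28 (permutation p = 0.426). The NTS1 spacer ran from 0 to 8.29 with r = 0.65 (permutation p = 0.0478) and rho = 0.62 (permutation p = 0.0616), or r = 0.89 without the strain with 208 repeats (exact permutation p = 0.00180), on 0 to 8 reads. The ratio of 25S to 18S rRNA had r = -0.32 (permutation p = 0.378) and rho = -0.24 (permutation p = 0.516). Adjusted over these 3 relations, the p for r was 0.378, 0.143 and 0.378, and that for rho 0.516, 0.185 and 0.516. Without the strains with 72 and 237 repeats r was 0.25, 0.47 and -0.18, and within series 0.16, 0.52 and -0.12.

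Chance could not be excluded for the calls in total RNA, the lists and the slope agreement. Of 100 assignments of repeat numbers to the strains, 14 gave at least the 1 limma call in total RNA (highest other 8). For lists, 10 gave at least the 13 lists in polyA RNA (highest other 15) and 38 at least the 5 lists in total RNA (highest other 11). For the slope agreement 40 gave an r as large as 0.25 (highest other 0.42). The counts of 0 limma calls in polyA RNA (highest other 4) and for the interaction (highest other 1) are met by all 100 assignments by construction, so this comparison says nothing about them. In polyA RNA 312 genes had an unadjusted p under 0.05 against a median of 177 and a range of 44 to 1105 over the other assignments; what sets the strains apart in the highest of these was not tested.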
